A study of Homo sapiens with 4 samples.

How the data were processed

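Human dermal microvascular endothelial cells were left untreated or treated for 24 h with U1, with LL-37 or with both. Per the labels' protocols, libraries were made from 1000 ng of total RNA with a TruSeq RNA kit. Each of the 4 groups had 1 library, and groups were taken from the sample labels. The submitters' processing notes name the aligner TopHat2 2.0.8 and the statistics package Partek, with no version. They also name the build mm10, a mouse build, although the cells and the gene names are human, so no coordinates are given. The quantifier, the annotation, the strand setting and the normalisation are not given in the sources used here. Genes that overlap on opposite strands could therefore not be told apart, nor could close paralogs or a gene and its pseudogenes.

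Per the file headers, each treatment had a table of genes against the untreated library. No fold in these tables was below 1.5. The deposited signal values are least squares means of normalised reads per gene and library, fractional and never negative. The deposited total reads are estimated counts of a gene over a set of libraries that the tables do not name. They held 1 number per gene in every table for all 142 genes in 2 or 3 tables, and exceeded the sum of the treated and untreated values for every gene. The deposited p-value and its step-up adjustment compare the treated with the untreated library. An unadjusted p equal, within 1%, to a Wald test of a Poisson model with the 2 values as counts was found for 203 of 204, 171 of 173 and 513 of 516 genes after U1, LL-37 and U1 + LL-37. The deposited ratio is the treated over the untreated value. The deposited fold change is a signed score, minus the inverse of the ratio below 1. Folds computed here from the values differed from it by 0.0% at most. The adjusted over the unadjusted p of the first gene gives 7240 genes tested in each comparison. Per the file headers, the gene ontology table gives for each term an enrichment score, which equals minus the natural log of its p-value, and 4 numbers of genes. The deposited p-values equalled an upper-tail hypergeometric probability within 1% in 2578 of 2578 terms. The 98 listed genes are as many as the protein coding genes above 2-fold in the combined table.

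The tables held 205, 174 and 518 genes, and 1, 1 and 2 of them were left out under the rules for human samples. Names were matched to GENCODE release 29 and then to RefSeq symbols and older names. This gave a gene class for 97 of 204, 85 of 173 and 378 of 516 genes, or 47.5%, 49.1% and 73.3%. Most of the rest have clone names and are counted but not named. Unlisted genes either differed by less than 1.5-fold or were not among the genes tested, and the tables do not tell these apart.

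With 1 library per group no test between conditions was possible. The ratio of each pair of values was given an exact 95% interval (Clopper-Pearson, from the share of the treated value in the sum of both), which treats fractional normalised values as read counts and covers counting error only. PCR reads without molecular identifiers are not independent molecules, so the true error is larger. The library totals are unknown, and the highest untreated value on any list was 1757. Lists of genes for pathways, complexes and cell types, 40 in all with 851 symbols, were counted by direction. The median ratio of the listed members of a list was placed among 10000 random sets of the same size. These were drawn from the same table within 5 bins of mean value. Sets drawn without bins were run as well. Overlaps of lists were set beside the number that independent lists would share, which is the product of their sizes over 7240.

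The gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, per comparison, the 12 genes with the highest and the 8 with the lowest fold among those with a symbol, and up to 4 members with the largest fold of each list with 2 or more listed members. Across comparisons it takes the 8 genes with the highest and the 4 with the lowest fold after U1 + LL-37 on neither other list, up to 6 genes on all 3 lists and up to 6 in opposite directions. A gene named outside it is said to have been chosen after its values were seen. Where 5 or fewer members of a list were listed, all may be named. Some genes that the rule takes are not reported here.

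Alternatives were folds of 2 and 3, the authors' unadjusted and adjusted p below 0.05, a higher value of at least 1, folds with a pseudocount of 1, older and newer symbols, and gene ontology terms with at least 5 listed genes or a Benjamini-Hochberg adjusted p below 0.05. Intervals that exclude 1, a fold of 2 for shared genes, the matched random sets and 5 alternatives for interferon-stimulated genes were added after seeing the data. The intervals were tested on simulated reads, 50 times per comparison, with the untreated values as means. They held the true ratio in 98.7%, 98.9% and 98.6% of cases for the 204, 173 and 516 genes of U1, LL-37 and U1 + LL-37. Unchanged genes had an interval that excluded 1 in 0.943%, 0.639% and 1.27% of cases. A 4-fold change was found in 47.9%, 40.2% and 52.1% of cases, and a 16-fold change in 98.1%, 99.2% and 99.4%. Simulated pairs in which either side had no reads were left out, so all these shares hold for the remaining pairs. The simulation used whole counts and no 1.5-fold limit, unlike the deposited values. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.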

Results

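Human dermal microvascular endothelial cells, primary cells that line the small vessels of the skin, were left untreated or treated for 24 h. The 3 treatments were U1, a double-stranded RNA named after the U1 small nuclear RNA of the spliceosome; LL-37, the antimicrobial peptide released from human cathelicidin; and both together. RNA was sequenced from 4 libraries, 1 per group, so no difference had a replicate check. The deposited data were 3 tables of genes at 1.5-fold or more against the same untreated library, and 1 table of gene ontology terms. After exclusions the tables held 204 genes for U1, 173 for LL-37 and 516 for U1 + LL-37, each out of 7240 genes tested. Values were normalised read numbers per gene and library, with the normalisation not stated. Most were small: the median untreated value was 1.85 in the U1 table, 1.78 in the LL-37 table and 2.52 in the combined table. A ratio is followed by its 95% interval or by whether that interval included 1, and the interval treats the values as read counts and covers counting error only. The total depth of each library is unknown, since unlisted genes were not analysed here.

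Cells treated with U1 and LL-37 together had 282 genes listed higher and 234 listed lower than untreated cells. The 5 genes with the highest ratios were interferon-stimulated genes, which encode antiviral proteins. IFIT3, which encodes a protein of the antiviral IFIT family, had a value of 62.2 against 0.836, a ratio of 74.5 (interval from 11.4 upward, with the upper bound set by less than 1 untreated read). IFI6 stood at 165 against 3.16, a ratio of 52.1 (18.0 to 241). ISG15, a ubiquitin-like protein joined to other proteins during antiviral responses, stood at 917 against 25.1, a ratio of 36.5 (24.6 to 56.6). OAS3, which makes the oligoadenylates that activate RNase L when it binds double-stranded RNA, had a ratio of 23.2 (5.49 to 259), and IFI35 one of 22.6 (4.64 to 395). Of the 64 interferon-stimulated genes fixed beforehand, 30 were listed higher and 0 lower. The interval excluded 1 for 24 of the 30, and their median ratio was 8.0, at percentile 100 of 10000 random sets of listed genes matched on mean value. USP18, which removes ISG15 from proteins, had a ratio of 13.7 (1.44 to 2958), and UBE2L6, the enzyme that conjugates ISG15, also one of 13.7 (2.79 to 214). APOL1, IFI44 and HELZ2 had ratios of 13.9 (2.81 to 218), 13.7 (3.32 to 129) and 13.2 (3.64 to 91.3). The other 34 members, such as MX1 and IFIT1, were not on the list analysed here. They either differed by less than 1.5-fold or were not among the genes tested. A gene with few untreated reads may be unlisted whatever its change.

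**Figure D1:**
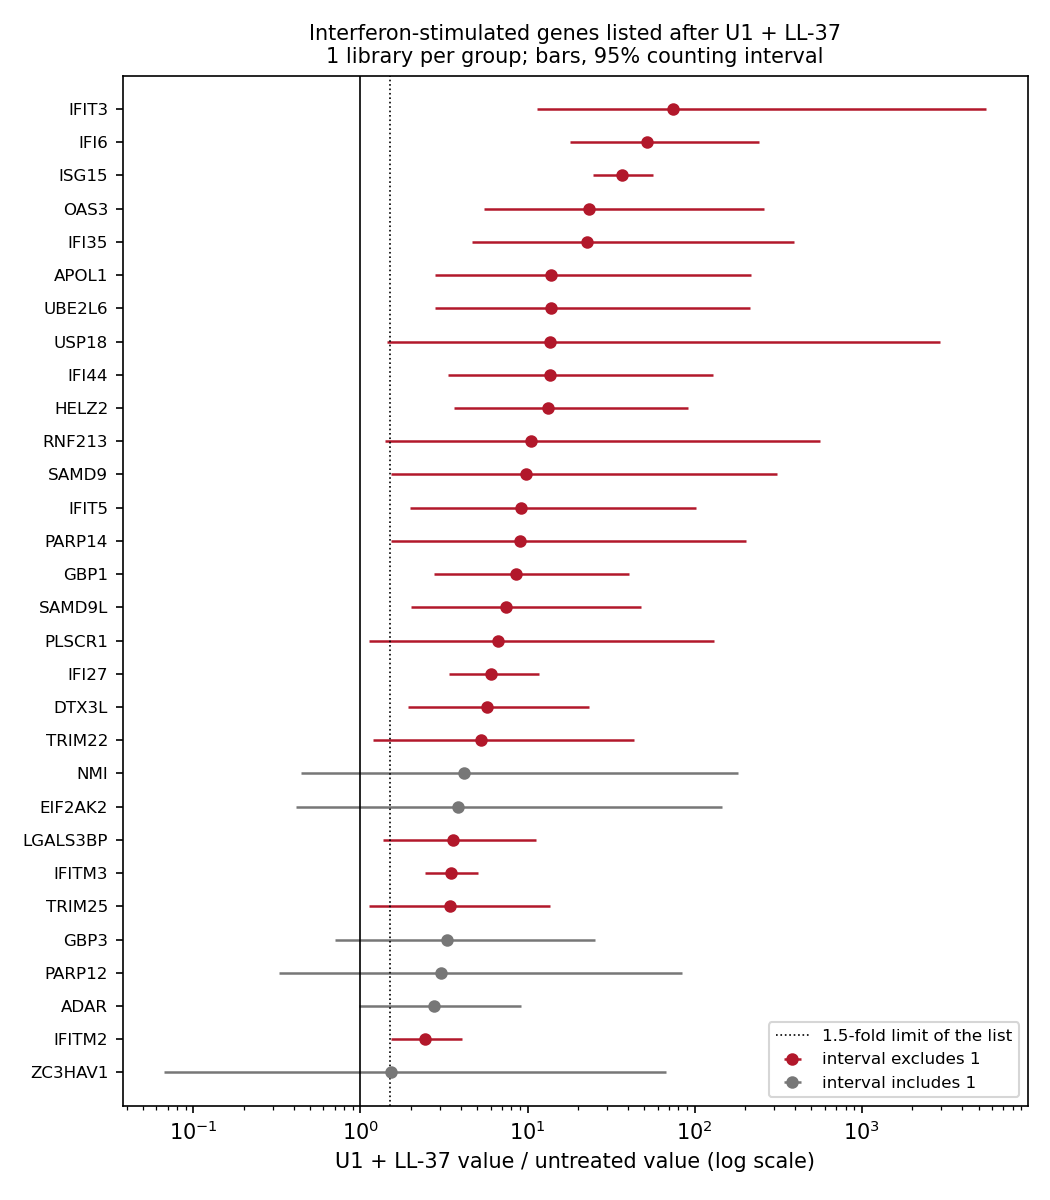
Each point is the ratio of the value after U1 + LL-37 to the untreated value, on a log axis, for the 30 listed interferon-stimulated genes; 1 library stands behind each value and bars are 95% counting intervals. Ratios run from 1.51 to 74.5, and 24 intervals (red) exclude 1 while 6 (grey) include it.

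Genes that carry the interferon signal were listed higher with them. Of 13 fixed members, 6 were listed higher and 0 lower: IRF7, the transcription factor that amplifies interferon production, had a ratio of 15.2 (4.5 to 91.6). STAT2, a transcription factor of type I interferon signalling that binds IRF9, had a ratio of 6.56 (1.93 to 34.9). The interval excluded 1 for 3 of the 6, and that of IRF1, at 3.13, included it. The median of the 6 was 4.84, at percentile 97.2 of the matched random sets. No interferon gene or interferon receptor of the 15 fixed was listed. No listed gene had an untreated value below 0.573, so genes under that value may be absent whatever their change. Among 19 nucleic acid sensors, 3 were listed higher: TREX1, a DNA exonuclease, at 3.93 (1.24 to 16.7), the double-stranded RNA kinase EIF2AK2 at 3.85 (0.414 to 146) and IFI16 at 2.5 (0.835 to 8.89). The median of these 3 lay at percentile 93.4 of the matched sets.

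Antigen presentation genes formed the next group. Of 19 fixed MHC class I and immunoproteasome genes, 6 were listed higher and 0 lower, with intervals excluding 1 for 4. B2M, the light chain of MHC class I, stood at 247 against 119, a ratio of 2.07 (1.66 to 2.60). The immunoproteasome subunit PSMB10 had a ratio of 3.07 (1.27 to 8.42), and the proteasome activator subunits PSME2 and PSME1 had ratios of 2.92 (1.22 to 7.90) and 2.32 (1.41 to 3.93). Their median ratio of 2.20 lay at percentile 70.7 of the matched sets, and at 95.3 of sets not matched on mean value. None of the 11 MHC class II genes was listed. LGALS9, a galectin that binds a checkpoint receptor of T cells, had a ratio of 12.7 (3.43 to 90.8), and CD274, which encodes PD-L1, 1.5 (0.129 to 26.5). CD68, a lysosomal protein used as a macrophage marker, was the 1 listed member of 19 leukocyte markers, at 40.9 against 8.40 (ratio 4.86, interval 2.28 to 11.7).

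Of the inflammatory, cell death and vascular genes named next, PROCR had an interval that excluded 1, and the intervals of the others included it. Among 29 chemokines, CXCL1 was 1.92-fold lower and IL8 was 1.76-fold lower, and 0 were listed higher. Among 25 cytokines and growth factors, CSF1 was 2.10-fold higher, TNFSF18 1.81-fold, LIF 1.71-fold and IL6 1.66-fold higher, and TNFSF15 was 1.99-fold lower. Among 28 genes of cell death and the inflammasome, 5 were listed higher, with MLKL at 3.09-fold and GSDMD at 2.71-fold. The decoy receptor TNFRSF10D was 4.93-fold lower. Of 20 angiogenesis and tip cell genes, ANGPTL4 was 2.04-fold higher, and CXCR4, TNFSF15 and VASH1 were 1.98-, 1.99- and 1.65-fold lower. Of 22 genes of coagulation and vascular tone, PROCR, the endothelial receptor of protein C, stood at 58.2 against 37.2, a ratio of 1.56 (1.02 to 2.43). PTGS2 was 2.19-fold higher, and PLAU and F2RL1 were 1.72- and 1.52-fold lower. Among 15 arterial and Notch genes HES4 was 2.49-fold higher and EFNB2 and HEY1 were 1.56- and 1.5-fold lower. Among matched random sets, the medians of the listed members lay at percentile 2.08 for chemokines, 1.65 for angiogenesis and 20.9 for coagulation genes. These medians rest on 2 of 29, 4 of 20 and 4 of 22 members, so they do not describe the whole lists. Medians of listed members lay at 72.3 for cytokines, 82.5 for cell death and 61.1 for arterial and Notch genes.

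Among lists with 0 members listed higher were p53 targets, with CCNG1, TP53INP1 and ZMAT3 at 1.5-, 1.57- and 2.33-fold lower of 22, and cholesterol biosynthesis, with MSMO1, SC5D and DHCR7 at 1.74-, 1.68- and 1.52-fold lower of 27. The interval of each of these 6 included 1. NOG, a secreted antagonist of bone morphogenetic proteins, was 4.19-fold lower and ACO1, the cytosolic aconitase, 3.38-fold lower, both with intervals that included 1. FABP4, a fatty acid binding protein of capillary endothelium, was chosen after its values were seen as the 1 protein coding gene listed lower whose interval excluded 1. It stood at 21.5 against 45.1, 2.10-fold lower (1.23 to 3.70). Of unchanged simulated genes 1.27% also had an interval that excluded 1, so 1 such gene among 87 may come from counting error. None of the 15 leukocyte adhesion molecules, 24 endothelial identity genes or 9 lymphatic markers was listed. The same held for 41 genes of mitosis, 41 of DNA replication, 26 immediate early genes, 26 of hypoxia and glycolysis, 24 of endoplasmic reticulum stress, 18 matrix proteases and 15 mitochondrially encoded genes. Markers of other skin and blood cells were not listed either, for keratinocytes (18), fibroblasts (12), pericytes and smooth muscle (11), red cells and platelets (9) and melanocytes (7). CXCL1 was the 1 listed member of 22 NF-kappaB response genes, and none of 29 ribosomal protein genes was listed. Single listed members of other lists were the histone HIST1H4K, 2.21-fold lower, and the scavenger receptor SCARB2, the metallothionein MT1M, the heat shock protein DNAJA1 and the collagen COL8A1, at 2.06-, 2.92-, 1.65- and 1.63-fold higher, all with intervals that included 1.

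In the authors' deposited table, 22 genes had an adjusted p below 0.05 after U1 + LL-37, and all 22 were listed higher. They included ISG15 (adjusted p 7.52e-67), IFI6 (2.41e-09) and B2M (4.28e-08). These p-values equal, within 1%, a Wald test of a Poisson model with 1 library per side for 513 of 516 genes. They compare the reads of 2 libraries and not the conditions.

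The gene ontology table described 98 genes listed higher after U1 + LL-37, in 2578 terms. In the authors' deposited table, response to virus held 25 of the 98 genes against 245 of a background of 18440, with p = 2.03e-25 in an exact upper-tail hypergeometric test, and defense response to virus held 21 (p = 5.45e-24). The type I interferon signaling pathway held 15 of its 68 genes (p = 8.79e-21 in the authors' deposited table) and interferon-gamma-mediated signaling 13 of 77 (p = 1.65e-16). Antigen presentation through MHC class I held 7 of 104 genes (p = 1.34e-06 in the authors' deposited table). By that exact test toll-like receptor signaling held 5 of 129 genes (p = 0.000626 in the authors' deposited table) and inflammatory response 8 of 437 (p = 0.00229). After Benjamini-Hochberg adjustment of the deposited values over the 2578 terms, 300 terms were below 0.05, these 2 among them at 0.0108 and 0.0281. Terms above it by the same exact test were angiogenesis, with 4 of 254 genes (adjusted p = 0.156), NF-kappaB signaling, with 1 of 57 (0.406), and cell adhesion, with 6 of 1006 (0.568). The background exceeded the 7240 genes that could have been listed, which tends to make these p-values too small. Terms with weaker p-values, such as toll-like receptor signaling and inflammatory response, may therefore not hold. Genes are also not independent replicates.

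Cells treated with U1 alone had 119 genes listed higher and 85 lower, and 194 of the 204 intervals included 1. Interferon-stimulated genes were nearly absent from this list: of the 64 members only IFI6 was present, at 4.82 against 3.16, a ratio of 1.52 (0.296 to 9.41). GAPDHP44, a pseudogene of the glycolytic enzyme GAPDH, had the highest ratio, 15.7 (3.39 to 212), at 24.4 against 1.56. The authors' adjusted p for GAPDHP44 lay above 0.05. Among genes with a symbol GAPDHP44 was followed by RHOT1P1 at 4.37, the vascular microRNA gene MIR126 at 4.33 and SNORD99 at 3.61. The intervals of these followers included 1. Protein coding genes made up 6 of the 119 genes listed higher, and pseudogenes made up 52. How reads shared by a pseudogene and its parent gene were counted is not stated, so pseudogene values are uncertain. The 3 structural RNAs on the fixed list of 17 were listed lower. RMRP, the RNA of the mitochondrial RNA processing endoribonuclease, stood at 1.96 against 15.2, 7.72-fold lower (1.78 to 71.4). RN7SK, which holds the elongation factor P-TEFb inactive, was 5.33-fold lower (1.42 to 32.7), and RN7SL1, the RNA of the signal recognition particle, was 2.47-fold lower (1.59 to 3.94). In the authors' deposited table an adjusted p below 0.05 stood beside 4 genes, among them RN7SL1 (0.0298) and the pseudogene RPL41P1 (0.00412), which was chosen after its values were seen.

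Cells treated with LL-37 alone had 94 genes listed higher and 79 lower, and 166 of the 173 intervals included 1. None of the 64 interferon-stimulated genes was listed. TMSB10P1, a pseudogene of the actin-binding peptide thymosin beta 10, stood at 535 against 184, a ratio of 2.90 (2.45 to 3.45) with an adjusted p of 4.32e-32 in the authors' deposited table. It stood at 499 after U1 + LL-37, a ratio of 2.70 (2.28 to 3.22), and was not on the U1 list. PIGY, which takes part in glycolipid anchor synthesis, was chosen after its values were seen. It was the 1 of 8 listed protein coding genes whose interval excluded 1, at 25.6 against 11.9 (ratio 2.14, interval 1.04 to 4.67). MIR126 and SNORD99 had the highest ratios, 4.88 and 3.05, with intervals that included 1. Protein coding genes made up 3 of the 94 genes listed higher, and pseudogenes 40. RMRP was 7.92-fold lower (1.80 to 76.3), RN7SK 6.28-fold lower (1.55 to 47.2) and RN7SL1 2.01-fold lower (1.33 to 3.08). RPS29, a ribosomal protein gene, was 3.18-fold lower and HMGCS1, an enzyme of cholesterol synthesis, 1.58-fold lower, both with intervals that included 1.

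**Figure D2:**
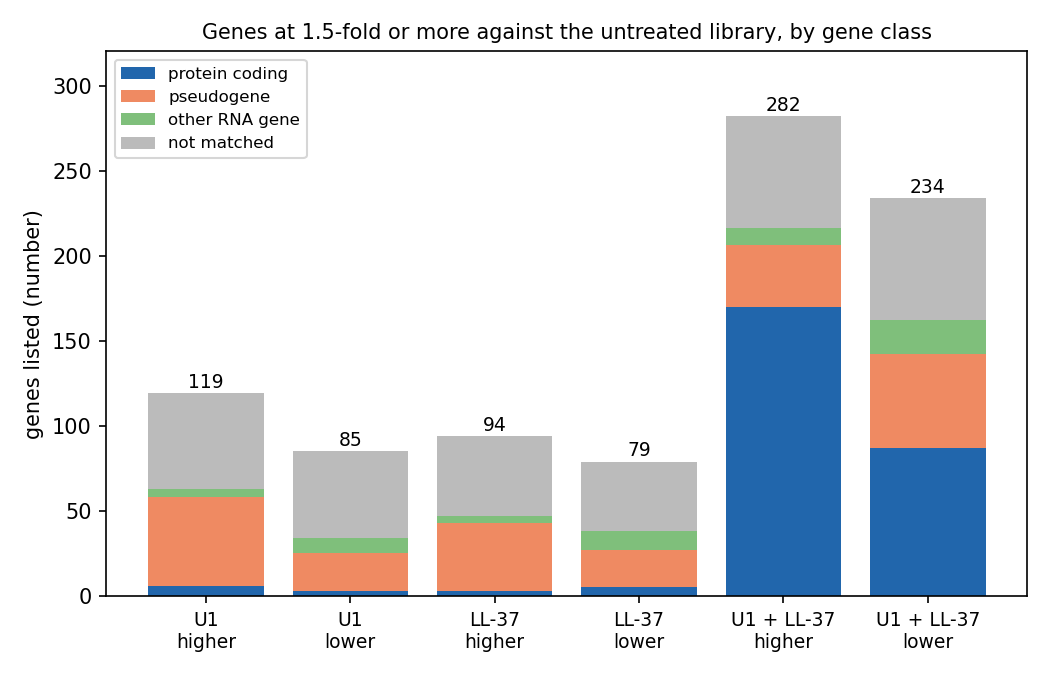
Bars give the number of genes listed at 1.5-fold or more against the untreated library after each treatment, by direction, with colours for the class of the gene in the reference annotation; genes not matched mostly have clone names. Protein coding genes are 170 of 282 listed higher after U1 + LL-37, 6 of 119 after U1 and 3 of 94 after LL-37.

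The lists were then set against each other to ask which genes the combined treatment shared with its parts. Of the genes listed higher after U1 + LL-37, 36 were also listed higher after U1 and 33 after LL-37; independent lists of these sizes would share 4.64 and 3.66. On the lower side 27 and 33 were shared, with 2.75 and 2.55 for independent lists. U1 and LL-37 shared 42 genes listed higher and 26 listed lower, with 1.55 and 0.927 for independent lists. All comparisons used 1 untreated library, so part or all of these excesses may come from it. The tables hold listed genes alone, so unchanged groups could not be simulated. On all 3 lists stood 40 genes, 38 of them in 1 direction, 21 higher and 17 lower. Among these MIR126, SNORD99 and FAM27A were listed higher, and RMRP, RN7SK and the pseudogene NPM1P18 were listed lower. RN7SL2, a second gene of the signal recognition particle RNA chosen after its values were seen, was 2.17-, 2.35- and 1.89-fold lower after U1, LL-37 and U1 + LL-37, with intervals that excluded 1. After the combined treatment RMRP was 3.54-fold lower (1.16 to 13.8), RN7SK 2.94-fold lower (0.996 to 10.6) and RN7SL1 1.69-fold lower (1.15 to 2.53). The median of these 3 lay at percentile 0.07 of the matched random sets, and at 0.51 after U1 and 0.55 after LL-37.

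**Figure D3:**
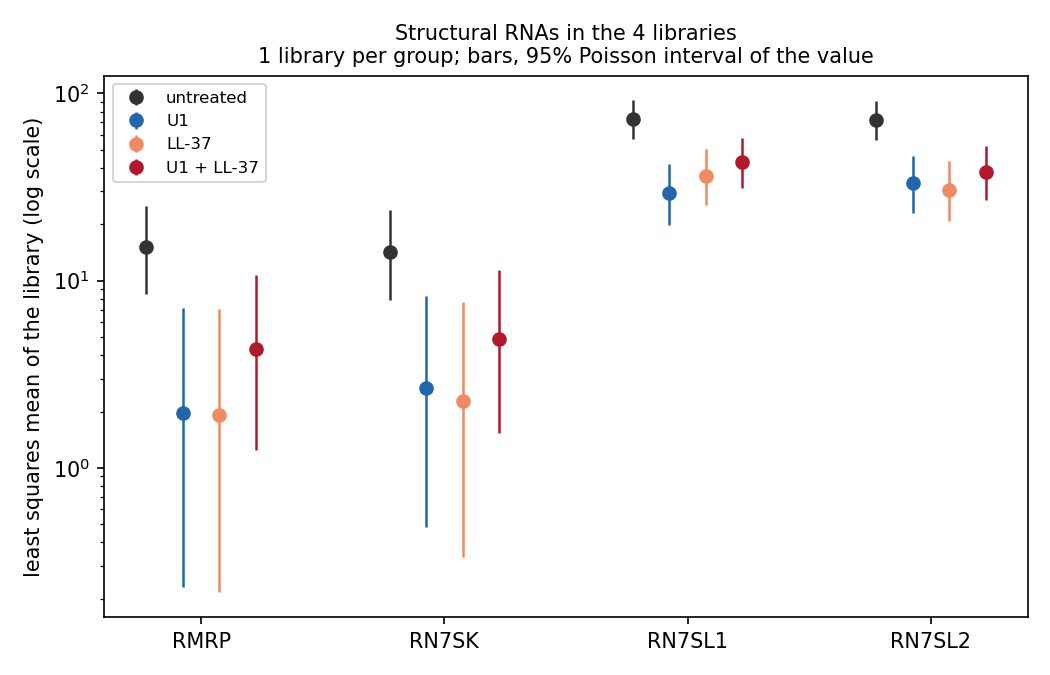
Points are the deposited values of 4 structural RNAs in the 4 libraries on a log axis, with 95% Poisson intervals that cover counting error only. The untreated library has the highest value for each RNA, from 14.3 for RN7SK to 73.0 for RN7SL1, and the treated libraries lie from 1.92 for RMRP after LL-37 to 43.1 for RN7SL1 after U1 + LL-37.

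Neither single-treatment list held 227 of the genes listed higher and 181 of those listed lower after U1 + LL-37, of which 169 and 85 were protein coding. The 8 with the highest ratios were IFIT3, ISG15, OAS3, IFI35, IFI30, IRF7, APOL1 and UBE2L6. IFI30, a lysosomal thiol reductase that prepares antigens, stood at 11.7 against 0.764, a ratio of 15.3 (1.88 to 1741). On the lower side RNU5B-4P, TNFRSF10D, NOG and ACO1 came first, at 6.57-, 4.93-, 4.19- and 3.38-fold lower, all with intervals that included 1. If the same 7240 genes entered each comparison, these genes lay within 1.5-fold of the untreated value after U1 alone and after LL-37 alone. For genes shared in 1 direction, the value after U1 + LL-37 was compared with the value after the single treatment. IFI6 alone had an interval that excluded 1, at 165 after U1 + LL-37 against 4.82 after U1, a ratio of 34.2 (14.2 to 109.6). Median log2 ratios of the combined to the single value lay between -0.09 and 0.08 for genes shared in 1 direction. These genes lay at least 1.5-fold from the same untreated value, on the same side, in both lists. Medians this small therefore follow in part from the selection.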

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

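Genes listed in opposite directions in 2 tables were picked out because the same contrast with untreated cells pointed opposite ways, and these differences were not tested between conditions. After U1 and after LL-37, 6 of the 74 genes on both lists were listed in opposite directions. After U1 and after U1 + LL-37 this held for 14 of 77, and after LL-37 and after U1 + LL-37 for 5 of 71. None of these genes had an interval that excluded 1 in both tables. The 6 with a symbol and the largest folds after U1 + LL-37 were the pseudogenes RPL31P49, KRT18P56, SLC2A3P1, ATP5A1P10, FDPSP2 and TXNP4. The ratio of the 2 treated libraries had an interval that excluded 1 for TXNP4, at 14.8 after U1 + LL-37 against 4.15 after LL-37 (ratio 3.58, interval 1.15 to 14.4). The same held for HNRNPA1P7, chosen after its values were seen, at 14.7 after U1 + LL-37 against 36.0 after U1 (ratio 0.409, interval 0.207 to 0.768). Genes in this group lay at least 1.5-fold from the same untreated value, on opposite sides, in the 2 lists. Ratios of treated libraries far from 1 therefore follow in part from the selection.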

How the results depend on the processing

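Intervals that exclude 1, the fold of 2 for shared genes, the matched random sets and, for interferon-stimulated genes, a fold of 3, the authors' p, a higher value of at least 1 and the pseudocount were chosen after seeing the data. With 1 library per group, no library could be left out, and the small values limit every count: at the median untreated value of 2.52 of the combined table, most folds lie within counting error. Of 106 comparisons of a result with an alternative, 35 stayed within 1.5 times (percentiles within 10 points) and 71 moved. Reversals were not looked for. The 35 include an alternative that counted every row, which repeats the main count by construction. Most alternatives keep part of a list, so the counts fall by construction. The 30 interferon-stimulated genes listed higher after U1 + LL-37 numbered 9 with the authors' adjusted p below 0.05, and between 24 and 30 under the other 7 alternatives run for them. Matching genes by another identifier was not run, since the tables hold names alone.

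In the order higher and lower after U1 (119 and 85 genes), after LL-37 (94 and 79) and after U1 + LL-37 (282 and 234), a fold of 2 left 31 and 26, 24 and 27, and 133 and 41 genes. A fold of 3 left 7 and 10, 2 and 7, and 65 and 9. The authors' unadjusted p below 0.05 left 4 and 6, 2 and 5, and 67 and 9, and their adjusted p 2 and 2, 1 and 1, and 22 and 0. Folds with a pseudocount of 1 left 60 and 30, 33 and 35, and 179 and 86. Intervals that exclude 1 left 4 and 6, 2 and 5, and 64 and 6.

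Among genes listed higher after U1 + LL-37, those shared with U1 (36), with LL-37 (33) and with both (21), and those on neither other list (227), numbered 11, 6, 5 and 120 at a fold of 2 in each list. They numbered 15, 10, 9 and 116 with 2-fold asked of the combined treatment alone, and 0, 1, 0 and 63 where intervals exclude 1 in each list. On the lower side the same groups, of 27, 33, 17 and 181 genes, numbered 7, 5, 5 and 34, then 13, 12, 8 and 21, then 3, 3, 3 and 3. Genes shared in 1 direction by the combined list and a single treatment list, 129 over both pairs of lists, numbered 29 at a fold of 2.

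Members of any fixed list after U1 + LL-37, 84 in both directions, numbered 37 where intervals exclude 1, of which 35 of 64 were listed higher and 2 of 20 lower. At a fold of 2, 5 of the 20 listed lower were left. Gene ontology terms, 2578 in all, numbered 300 with an adjusted p below 0.05 and 535 with at least 5 listed genes. On random sets matched on mean value, the percentile of the median of the listed members moved from 95.3 to 70.7 for MHC class I genes. It moved from 43.4 to 61.1 for arterial and Notch genes and from 39.6 to 20.9 for coagulation genes.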

Other observations

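All tests in this part were chosen after the results they bear on were seen, and so were the genes named in the next paragraphs.

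Beyond the fixed lists, the combined treatment had 106 protein coding genes listed higher, of which 17 had an interval that excluded 1, and 70 listed lower, of which 1 did. The intervals carry no adjustment for the number of genes tested. Of the 17 genes, those named in this paragraph and the next with an authors' adjusted p below 0.05 were MYD88 and LY6E. Counting error stays open for each of the others taken alone. MYD88, the adaptor of Toll-like receptors, stood at 55.2 against 15.0 (ratio 3.69, interval 2.06 to 7.04). UBA7, the enzyme that activates ISG15 for conjugation, had a ratio of 7.28 (2.04 to 43.3), so the activating enzyme, the conjugating enzyme UBE2L6 and the protease USP18 were all listed higher with ISG15 itself. LY6E, a membrane protein that restricts coronavirus entry, stood at 67.2 against 9.51 (ratio 7.07, interval 3.57 to 15.7). C19orf66, an inhibitor of viral translation, had a ratio of 5.33 (1.90 to 19.6), and TRIM21, a cytosolic antibody receptor, one of 4.62 (1.35 to 23.2). IL18BP, the secreted inhibitor of interleukin 18, had a ratio of 6.25 (1.07 to 111).

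The leucine aminopeptidase LAP3 had a ratio of 6.58 (1.59 to 52.5), and TYMP, the thymidine phosphorylase also known as an endothelial growth factor, one of 10.4 (1.52 to 425). WARS, the tryptophan tRNA ligase, stood at 25.2 against 7.40 (ratio 3.40, interval 1.46 to 9.06). The lysosomal proteases CTSS and LGMN, at 2.68 and 2.52, had intervals that included 1. The 4 GTPases GIMAP2, GIMAP8, GIMAP4 and GIMAP7 had ratios of 1.91, 1.72, 1.58 and 1.5, and each interval included 1. MDK, a heparin-binding growth factor, stood at 50.2 against 23.3 (ratio 2.15, interval 1.29 to 3.68), and the crosslinking enzyme TGM2 at 44.4 against 25.8 (ratio 1.72, interval 1.04 to 2.92). On the lower side FABP5, a fatty acid binding protein, stood at 19.4 against 30.7, 1.58-fold lower, with an interval that included 1 (0.866 to 2.95).

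Interferon-stimulated genes stood higher after U1 + LL-37 and were nearly absent from both single treatment lists. Counting error alone would put few members past their interval, and 24 of the 64 fixed members had an interval that excluded 1 on the higher side. A low value in the shared untreated library alone would leave the other libraries as high as the combined one, and total reads over the combined value as large as for genes with small differences. In 29 of the 30 listed members this quotient lay below the lowest, 3.71, of 341 other genes listed at under 2-fold in either direction. Its median was 1.77, against 9.31 for these 341 and 4.79 for the 252 other genes listed higher. With IFI6 at 4.82 after U1 against 165 after both, these values argue against a low untreated library for those 29. Whether the combined library differs through the treatment or for a reason of its own stays open, since it has no replicate and the libraries that the totals cover are not named.

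RMRP, RN7SK and RN7SL1, structural RNAs without long poly(A) tails, stood lower after each of the 3 treatments. Of the 17 fixed members, an interval excluded 1 for 3 after U1, 3 after LL-37 and 2 after U1 + LL-37. After U1 + LL-37 the interval of RN7SK included 1. These intervals are not adjusted for the number of genes tested. The authors' adjusted p lay below 0.05 for RN7SL1 in the U1 table only. For RMRP and RN7SK it lay below 0.05 in no table. Counting error therefore stays open for RMRP and RN7SK, and for RN7SL1 after LL-37 and after U1 + LL-37. A high value in the shared untreated library cannot be told apart from an effect common to all treatments, because 0 of 9 ratios between treated libraries had an interval that excluded 1 and both explanations give this. The untreated value was 15.2 beside 29.4 total reads for RMRP, 14.3 beside 33.3 for RN7SK and 73.0 beside 289 for RN7SL1. Total reads over the sum of the 4 values were 1.26, 1.38 and 1.59, below the median of 1.93 for the 40 genes on all 3 lists. A high untreated value would lower this quotient, but the scale and the libraries of these totals are unknown, so it does not decide. How well each preparation removed RNAs without poly(A) tails could be a further source, and no value here tests it.

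Pseudogenes made up 91 of the 516 genes listed after U1 + LL-37, and a candidate explanation for some is reads shared with the parent gene. Of 83 with a parent name, 74 had a parent that was not listed, for which this stays open; for the rest the parent was listed in the same direction in 9 of 9 pairs from 7 parents, and the folds of a pair differed by a median of 0.07 and at most 0.22 on the log2 scale. LAP3P2 stood at 62.1 against 9.65 and LAP3 at 14.4 against 2.18, folds of 6.44 and 6.58, and in 7 of the 9 pairs the pseudogene had the higher value. In these pairs reads of an expressed gene may be counted partly on its pseudogene. After U1 or LL-37 alone 0 of 98 pseudogenes with a parent name had a listed parent, so it stays open whether GAPDHP44 and TMSB10P1 follow their parent genes.

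In each table the lowest untreated value was 0.573, and 23 of the 893 treated values over the 3 tables lay below it.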
